A study of Mus musculus with 18 samples.

How the data were processed

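Gene expression was measured on 18 Affymetrix arrays from mouse cells of strain C57/B6: embryonic stem (ES) cells, neural progenitors and neurons, each with both Hmgn1 alleles intact (+/+) or both inactivated (-/-), with 3 arrays in each of the 6 groups. Per the labels, ES cells grew in medium with LIF and serum replacement, either on mitotically inactivated embryonic fibroblasts or without feeders. Which arrays came from which of these conditions is not stated. The neural cells were made from ES cells with a commercial kit for dopaminergic neurons, and each array received labelled cRNA made from 6 ug of total RNA. The labels call the 3 arrays of a group biological replicates, and whether they were separate cultures or separate differentiation runs is not stated. The p-values therefore measure only the spread between the arrays as deposited, which may be technical. How many ES cell lines stood for each genotype is not stated either. A genotype effect below is thus a difference between the -/- and +/+ groups, and other differences between the lines cannot be told apart from the loss of Hmgn1.

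The deposited values are an intensity per probe set on a linear scale, produced by the authors with RMA and limma per the submitters' processing notes, whose versions and settings are not given in the sources used here. A probe set is the group of short probes on the array that reads 1 transcript. The values ran from 5.5 to 27824, the array medians from 55.7 to 60.5, and no 2 arrays were identical. All 18 columns belonged to a described sample. An array has no counting depth, so the number of arrays limits the precision, together with the background: the 40th percentile of an array, used below as the lower bound for signal, lay between intensities of 36.6 and 38.7. Values were taken to log2(value + 1), the form planned for the case of linear values.

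Of 45101 probe sets, 64 were array controls, 9211 had no gene symbol in the probe table used, 932 had several symbols and 34958 had exactly 1. Only those with 1 symbol entered the gene tests. A probe set was kept when it reached the 40th percentile of its array on at least 3 of the 18 arrays, which left 26324. For each gene the probe set with the highest mean log2 value over all arrays was used, which gave 14433 tested genes of the 18194 with a probe set. For 6825 of the tested genes this was a choice among several probe sets. The probe sets with no single symbol were tested apart, with the same filter.

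Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes), with 6 group means over all 18 arrays and 12 residual degrees of freedom. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, within 1 comparison. The comparisons were -/- against +/+ in each of the 3 cell types, neural progenitors against ES cells and neurons against neural progenitors in each genotype, and the difference between the genotype effects of each pair of cell types (the interaction). Changes are given as log2 differences with their standard error (SE) from the fit, always -/- minus +/+ or the later stage minus the earlier, and n is 3 arrays per group. Adjusted p-values, unless named otherwise, are from limma. Effects were also correlated across genes between comparisons that share no arrays, as a description, since genes are not independent replicates. The SE of these correlations came from a jackknife over arrays. Overlaps of called genes were tested with a two-sided Fisher exact test among all tested genes.

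The named genes followed a fixed rule. For each genotype comparison these were the 10 largest rises and the 10 largest falls among called genes whose 3 -/- arrays lay all above or all below the 3 +/+ arrays. For each differentiation step in +/+ cells the rule took the 6 largest in each direction, for each interaction the 5 largest in each direction, and for each gene list and comparison up to 4 called members with the largest change. Every member of the HMGN family among the tested genes was reported, and symbols that are only clone or sequence identifiers were passed over. Any list member that did not pass could be named with its value. Hmgn1 itself was also read from each of its probe sets on every array.

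The 30 gene lists, with 704 entries in all, were fixed before the data were examined, as were the comparisons, the tests and the rule for named genes. They were the HMGN family, Linker histones, Naive and general pluripotency, Primed pluripotency, Two-cell-like, Neural progenitor, Midbrain dopaminergic patterning and identity, Pan-neuronal, Glutamatergic and GABAergic transmission, Astroglia, Oligodendrocyte lineage, Fibroblast and mesenchyme (feeder cells), Endoderm and visceral endoderm, Mesoderm and cardiac, Neural crest and peripheral neuron, Endothelial and blood, Cell cycle, Hox genes, Imprinted genes, Sex-linked (Xist and Y-linked), Genes near Hmgn1 on chromosome 16, Reported HMGN1-linked genes, p53 targets and DNA repair, Interferon response and MHC class I, Immediate early and heat shock, Amino acid and ER stress (ATF4 targets), Hypoxia and glycolysis, Cholesterol biosynthesis, DNA methylation and Polycomb, and Chromatin remodellers and histone variants. Each list was tested with limma's camera, which compares the list with all other genes, at a preset correlation between genes of 0.01, for the 3 genotype comparisons and the 2 steps in +/+ cells. P-values were adjusted over these 145 tests. Lists with fewer than 3 measured members were not tested. Each camera test was repeated with a correlation estimated from the list, and fry, which asks whether a list's genes move on balance to 1 side, was run beside it. Numbers of called members are given over all genes and adjusted over the list alone.

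Chromosomes were taken by gene symbol from a table of RefSeq genes on the assembly GRCm38.p6, which placed 14402 of the tested genes and left out 31. The build behind the deposited values is not given in the sources used here. One-sided Fisher exact tests compared each chromosome with the rest, adjusted over the chromosomes of all 3 genotype comparisons, separately for falls and rises. This look at chromosomes, and the lists of prolactin, serotonergic and placental genes in the closing section, were chosen after the data were seen.

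The alternatives fixed in advance were: only the arrays compared, a block for the replicate number, no filter and a stricter filter at the 60th percentile, quantile normalization within each cell type, centring each array on its median, raising values under the 25th percentile to it, all probe sets or their mean per gene, array weights, a variance trend with intensity, a fold change of at least 1.5, an adjusted p under 0.01, and leaving out each array in turn. No pseudocount, a pseudocount of 16, leaving out the genes of chromosome 14 and, for the list tests, leaving out Olig1 and Olig2 were added after the data were seen. The fit was tested on simulated data with 14433 genes, of which 200 were changed: 75 to 78% of changes of 0.5 in log2 and 98 to 100% of changes of 1 were called, and 3.89 to 8.33% of the calls were false. The simulated noise was independent and had the same spread in all groups for a given gene. It therefore says little about false calls in ES cells, whose arrays spread more widely than those of the other cell types. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.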

Results

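The 18 arrays fell into 6 groups of 3: ES cells, neural progenitors and neurons, each from Hmgn1 +/+ and Hmgn1 -/- cells. Hmgn1 encodes a nucleosome-binding protein that affects chromatin compaction and transcription. Arrays of the same group correlated at r 0.992 to 0.998 across genes, arrays of different genotypes within a cell type at 0.989 to 0.994, and arrays of different cell types at 0.688 to 0.885. The first principal component held 77.1% of the variance and the second 19.5%, and both separated the cell types. The third held 1.02% and separated the genotypes in neural progenitors and neurons. The array of +/+ ES cells, replicate 3, stood apart from its group. On it 32 genes differed more than 2-fold from the mean of its group mates, 30 of them above, against 0 to 12 genes on any other array. Log2 changes below are means of 3 arrays minus means of 3 arrays, with the SE from the fit. Of the 60 largest genotype changes, 18 had a group mean under the background bound (the 40th percentile of the arrays), so their size is uncertain: among them are those of Olig1, Olig2, Fhit and Tmem267 in ES cells, of Ctsj, Serpinb9g, Prl4a1 and Gulo in progenitors, and of Abcc9, Tph2, Gjb6 and Ankrd1 in neurons.

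The first question was whether the Hmgn1 signal itself differed between the genotypes. It was lower in -/- cells of every cell type but not absent. The 3 bright Hmgn1 probe sets fell in all cell types, by 1.24-fold to 1.47-fold, with no overlap between genotypes on any of them. Of these, 1 averaged an intensity of 10025 in +/+ and 7589 in -/- ES cells, 12293 and 8354.5 in progenitors, and 7959.2 and 5877.2 in neurons. The probe set used for the gene changed by -0.31 in ES cells (SE 0.05, adjusted p 0.000519), -0.33 in progenitors (adjusted p 7.48e-05) and -0.32 in neurons (adjusted p 0.000152). The remaining probe set, at intensities near the background, did not pass. Where the probes lie relative to the deleted part of the gene is not given in the sources used here, so the remaining signal says little about the allele. Hmgn5, an X-linked relative, rose in -/- ES cells by 0.38 (SE 0.06, adjusted p 0.000376), fell in -/- progenitors by 0.43 (adjusted p 1.85e-05) and fell in -/- neurons by 0.23 (adjusted p 0.0071). The call in neurons was lost with only the 6 neuron arrays in the fit. Hmgn3 had changes of -0.30, 0.20 and 0.19 that did not pass (adjusted p 0.477, 0.705 and 0.714), with a wide spread in +/+ ES cells (SD 0.89) that enters the fit of all 3. Without +/+ replicate 3 the change of Hmgn3 in ES cells was 0.21 (adjusted p 0.044), so its direction there rests on 1 array. With only the 6 progenitor arrays the change of Hmgn3 in progenitors passed (adjusted p 0.0151), and its other probe set rose there by 0.35 (adjusted p 0.0318 over all probe sets). Hmgn2 shared its probe set with other symbols and so was not among the tested genes. That probe set had changes of -0.05 in ES cells, -0.06 in progenitors and 0.02 in neurons. None passed (adjusted p 0.717, 0.690 and 0.916 over all probe sets).

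**Figure D1:**
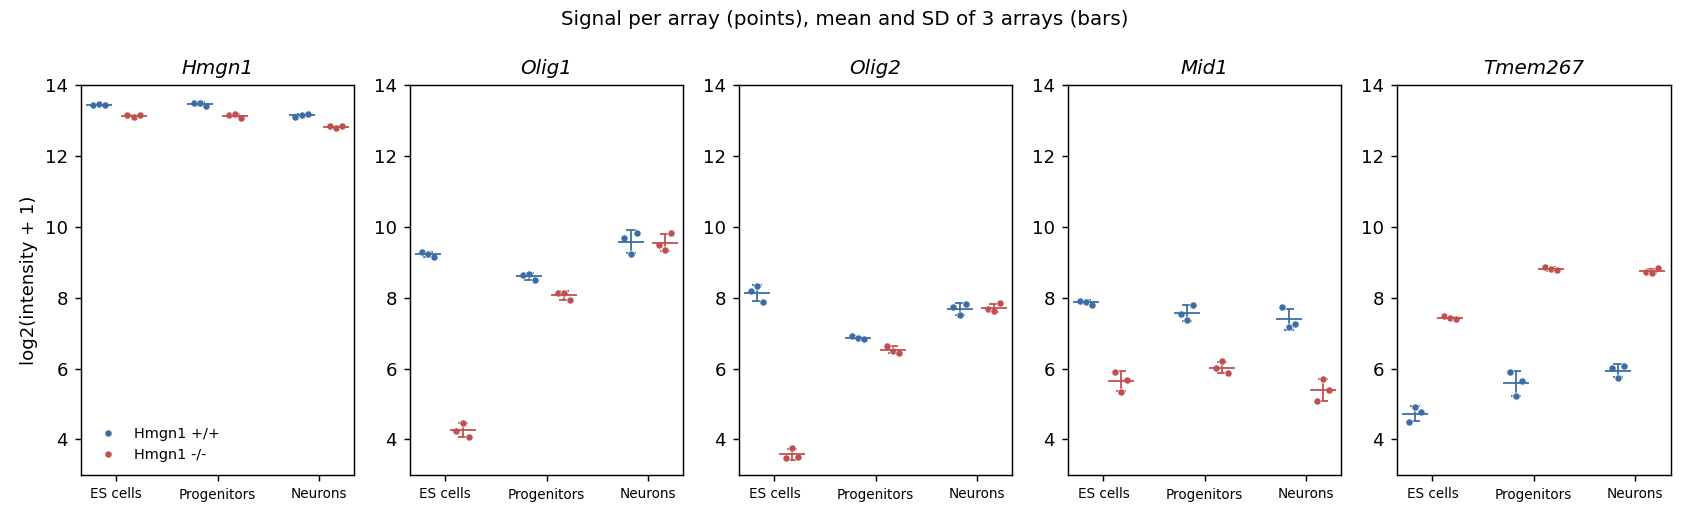
Signal of Hmgn1, Olig1, Olig2, Mid1 and Tmem267 on each of the 18 arrays as log2(intensity + 1), by cell type and genotype; points are arrays, bars the mean and SD of 3 arrays. Olig1 in ES cells lay between intensities of 561.8 and 629.8 in +/+ and between 15.9 and 21.2 in -/-, and Tmem267 and Mid1 were apart in all 3 cell types.

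Genes on chromosome 14 were lower in -/- cells of every cell type, and genes named below that lie there are marked. In ES cells 241 of its 493 tested genes fell (48.9%, adjusted p 2.77e-206, one-sided Fisher exact test), with a median change of -0.22, and they made up 38.6% of all genes that fell. In progenitors 159 fell (32.3%, median -0.13, adjusted p 3.21e-47), and in neurons 109 fell (22.1%, median -0.12, adjusted p 1.83e-25). On the other autosomes and the X chromosome the share that fell was 1.78 to 4.66%, 6.11 to 19% and 4.74 to 13% in the 3 cell types, with chromosome 12 at the top of each range. Without chromosome 14 the numbers of genes that rose and fell were 1426 and 362 in ES cells, 1085 and 1153 in progenitors, and 824 and 927 in neurons.

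**Figure D2:**
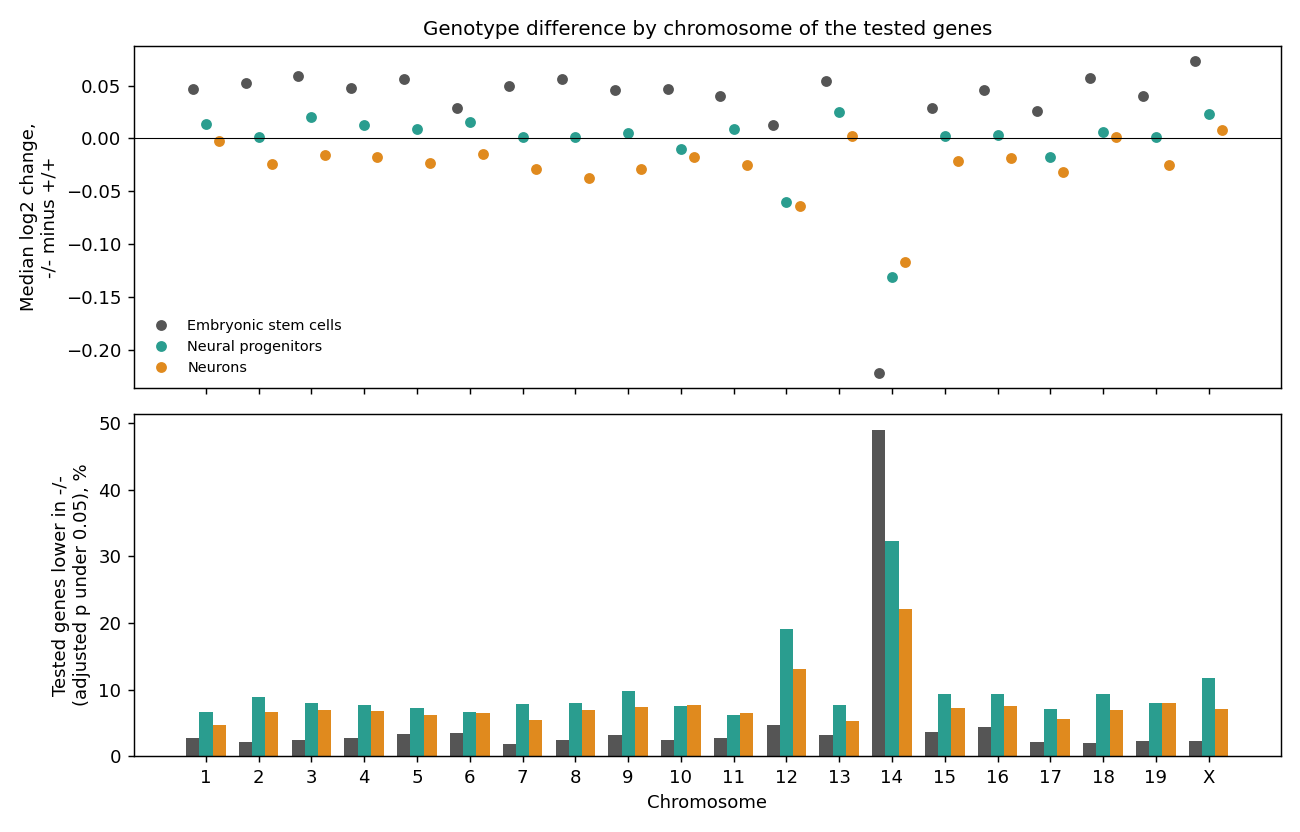
Genotype difference by chromosome for the 3 cell types: median log2 change, -/- minus +/+, of the tested genes (top) and the percentage of tested genes that fell at an adjusted p under 0.05 (bottom). Chromosome 14 has the lowest median in each cell type, -0.22 in ES cells, -0.13 in progenitors and -0.12 in neurons.

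In ES cells the comparison asked which genes differed between the genotypes before differentiation. The largest differences were near-complete losses of Olig1 and Olig2, transcription factors of the motor neuron and oligodendrocyte lineages. Olig1 fell by 4.96 (SE 0.14, adjusted p 1.53e-12) and Olig2 fell by 4.55 (SE 0.11, adjusted p 1.36e-13), from intensities of 235.5 to 317.8 for Olig2 in +/+ cells to 10.1 to 12.5 in -/- cells. The -/- values lay under the background bound, and down to that bound the falls are 3.94 for Olig1 and 2.85 for Olig2. Mid1, a microtubule-associated ubiquitin ligase, fell by 2.22 (SE 0.17, adjusted p 8.40e-07). The signalling ligand Bmp4 (chromosome 14) fell by 1.20, the fragile-site gene Fhit (chromosome 14) fell by 1.31, and the axon guidance gene Ntn1 fell by 0.91 (SE 0.06, adjusted p 1.18e-07). Tmem267, a little-studied membrane protein gene, rose by 2.70 (SE 0.13, adjusted p 3.49e-09), the Y-linked Uba1y by 1.73, Efhc2 by 1.40, the deubiquitinase Usp17la by 1.14 (SE 0.07, adjusted p 3.82e-08) and the kinase Pim2 by 0.96.

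The primed and the naive pluripotency genes were tested as separate lists in ES cells, and neither call held with an estimated correlation. Of 9 measured primed pluripotency genes, 6 rose and none fell (the same 6 and 0 adjusted over the list alone), with a median of 0.32 (adjusted p 0.0013, adjusted p = 0.121 with an estimated correlation). Fgf5, a marker of the epiblast, rose by 0.72 (SE 0.11, adjusted p 0.000602), Pou3f1 by 0.51 and Otx2 (chromosome 14) by 0.34. Of 32 naive and general pluripotency genes, 3 rose and 4 fell (3 and 7 adjusted over the list alone; adjusted p 0.0191, adjusted p = 0.198 with an estimated correlation). Leaving out +/+ replicate 1 ended this list's call (adjusted p 0.0912). Klf4, which sustains the naive state, fell by 0.63 (SE 0.07, adjusted p 8.19e-05) and Klf5 (chromosome 14) by 0.50. The two-cell-like list had 3 measured members, of which Usp17la and the arginase Arg2 rose, the second by 0.65 (adjusted p 0.0044, adjusted p = 0.142 with an estimated correlation).

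Several lists of other lineages were lower in -/- ES cells, while the mesoderm, endoderm and astroglial lists were not called (adjusted p 0.308, 0.394 and 0.701). The oligodendrocyte list was called (2 of 11 fell, Olig1 and Olig2, 1 rose and 3 fell adjusted over the list alone; adjusted p 0.00256, adjusted p = 0.198 with an estimated correlation), and so was the list of genes earlier reported as linked to HMGN1, which also holds both (1 of 12 rose and 2 fell, 2 and 2 adjusted over the list alone; median -0.21; adjusted p 0.000336, adjusted p = 0.0785 with an estimated correlation). Without Olig1 and Olig2 neither list was called (adjusted p 0.617 for the 9 others and 0.235 for the 10 others), though 7 of the 10 others of the second list lay below 0 (median -0.15). Of 33 mesenchymal genes, which mark feeder fibroblasts, 2 rose and 5 fell (median -0.11, adjusted p 0.00777, adjusted p = 0.577 with an estimated correlation), and quantile normalization ended that call (adjusted p 0.0521). Among them Col1a2, a collagen, fell by 0.48 and Fstl1 by 0.46. Of 14 neural crest genes 4 fell and none rose (2 rose and 4 fell adjusted over the list alone), with Dbh, which makes noradrenaline, at -0.50 and the receptor gene Ngfr at -0.41 (adjusted p 0.023, adjusted p = 0.100 with an estimated correlation). That call ended without +/+ replicate 3 (adjusted p 0.108) or without -/- replicate 3 (adjusted p 0.0923), and with quantile normalization (adjusted p 0.0912). The glutamatergic and GABAergic list had 1 of 14 lower, Gad1, which makes GABA, at -0.75, with another of its probe sets going the other way (adjusted p 0.0306, adjusted p = 0.192 with an estimated correlation). Its call ended without +/+ replicate 3 (adjusted p 0.0871), -/- replicate 2 (0.0561) or -/- replicate 3 (0.0807), and with quantile normalization (0.180). The Hox list, genes of body axis patterning, was lower as a set with a median of -0.12 and 1 of 15 members below the threshold (adjusted p 0.00478, adjusted p = 0.185 with an estimated correlation).

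Among the remaining lists in ES cells, the Y-linked genes Kdm5d, Eif2s3y and Uty rose by 0.72, 0.70 and 0.61 (3 of 5 sex-linked genes; adjusted p 0.00238, adjusted p = 0.0785 with an estimated correlation). Of 23 hypoxia and glycolysis genes 3 fell, among them the oxidoreductase Ero1a (chromosome 14) by 0.40 (adjusted p 0.00484, adjusted p = 0.429 with an estimated correlation). Of 23 immediate early and heat shock genes 1 rose and 2 fell, with Jun at -0.38 (adjusted p 0.013, adjusted p = 0.273 with an estimated correlation). That call ended without +/+ replicate 3 (adjusted p 0.0718). Lists that were not called included neural progenitor genes, of which 8 of 26 rose and 1 fell (adjusted p 0.107), with the stem cell marker Prom1 at 0.79. Cholesterol biosynthesis had 5 of 17 higher and 1 lower (adjusted p 0.0655), p53 targets and DNA repair 2 of 29 higher (7 adjusted over the list alone; adjusted p 0.483), the pan-neuronal genes 5 of 36 higher and 4 lower (adjusted p 0.334), and the cell cycle 1 of 31 lower (adjusted p 0.852). In all, 1520 genes rose and 624 fell in -/- ES cells (14.9% of the tested genes), 80 and 51 of them by at least 1.5-fold. With only the 6 ES cell arrays in the fit the number was 237, and many smaller changes named here, such as those of Pou3f1, Otx2, Klf5, Arg2, Col1a2, Dbh and Jun, did not pass. Quantile normalization gave 933 higher and 778 lower (54.5% higher, against 70.9%), and without +/+ replicate 3 there were 908 higher and 551 lower.

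In neural progenitors the genotypes parted along lineage markers. Endoderm genes fell together: 15 of 23 fell and 2 rose (the same adjusted over the list alone), with a median of -0.62 (adjusted p 1.29e-09, adjusted p = 0.0785 with an estimated correlation). The endoderm regulators Sox17, Sox7 (chromosome 14), Gata6 and Gata4 (chromosome 14) fell by 1.79 (SE 0.12, adjusted p 4.26e-08), 1.79, 1.64 (SE 0.15, adjusted p 7.08e-07) and 1.38. Mesenchymal genes rose: 27 of 33 rose and 1 fell (29 and 1 adjusted over the list alone), with a median of 0.68 (adjusted p 6.53e-20, adjusted p = 0.079 with an estimated correlation). The matrix gene Tgfbi rose by 1.95 (SE 0.14, adjusted p 4.96e-08), the pericyte receptor Pdgfrb by 1.49 and Thy1 by 1.23. The mesenchymal genes also mark fibroblasts, the cell type used as feeders in some of the ES cell cultures.

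The genes with the largest single differences in -/- progenitors came from several tissues. Tmem267 rose by 3.23 (SE 0.13, adjusted p 1.48e-10). The placental prolactin genes Prl7b1, Prl7d1, Prl2a1 and Prl4a1 rose by 2.53, 2.47, 2.43 and 1.88, and the placental protease gene Ctsj by 2.26. The lipid carrier Apod rose by 2.16 (SE 0.08, adjusted p 2.80e-11), Serpinb9g by 2.11 and the calcification inhibitor Mgp by 1.99. The prostaglandin receptor Ptger3 fell by 2.87 (SE 0.14, adjusted p 7.28e-10), Car8 by 2.24, the peptidase Enpep by 2.06, the water channel Aqp8 by 1.99, Gulo (chromosome 14), which acts in vitamin C synthesis, by 1.90, the collagen hydroxylase P4ha2 by 1.85 and the Wnt inhibitor Dkk1 by 1.82.

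The list for the midbrain dopaminergic lineage, the target of the protocol, was higher in -/- progenitors, on the same arrays on which endoderm genes were lower and mesenchymal genes higher. Of 24 members 10 rose and 1 fell (11 and 1 adjusted over the list alone; median 0.22; adjusted p 4.15e-05, adjusted p = 0.0785 with an estimated correlation). Aldh1a1, a retinaldehyde dehydrogenase of dopaminergic neurons, rose by 1.70 (SE 0.12, adjusted p 6.38e-08), the floor plate genes Foxa1 and Shh by 1.43 (SE 0.14) and 1.31 (SE 0.13), and the midbrain gene En1 by 1.21. Residual pluripotency genes were lower: 14 of 32 fell and 1 rose (2 and 15 adjusted over the list alone; median -0.26; adjusted p 4.93e-06, adjusted p = 0.0541 with an estimated correlation), with Fbxo15 at -1.71 (adjusted p 1.30e-10) and Klf4 at -1.09. Of 23 interferon and MHC class I genes 14 rose and 1 fell (16 and 1 adjusted over the list alone; median 0.38; adjusted p 2.15e-07, adjusted p = 0.0893 with an estimated correlation), among them the antiviral genes Usp18 at 1.22 (adjusted p 5.80e-06), Ifitm3 at 1.04 and Ifit1 at 0.95. Of 14 glutamatergic and GABAergic genes 5 fell, with the forebrain interneuron gene Dlx1 at -0.90 (adjusted p 0.0128, adjusted p = 0.122 with an estimated correlation).

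Further lists differed in progenitors by smaller amounts. Of 31 imprinted genes 7 rose and none fell (adjusted p 0.00131, adjusted p = 0.0893 with an estimated correlation), with Asb4 at 1.13 and the growth genes Grb10 and Igf2 at 0.55 and 0.51. Of 17 cholesterol biosynthesis genes 6 rose, such as the synthase Fdps by 0.28 (7 and 2 adjusted over the list alone; adjusted p 0.00777, adjusted p = 0.198 with an estimated correlation). The 3 Y-linked genes rose again, Kdm5d by 0.61 and Uty by 0.53 (adjusted p 0.0125, adjusted p = 0.100 with an estimated correlation). The HMGN list itself, with Hmgn1 and Hmgn5 lower among 3 measured members, was lower (adjusted p 0.0285, adjusted p = 0.196 with an estimated correlation). Hmgn1 is the targeted gene and Hmgn3 had a change of 0.20 that did not pass, so this list's call says little about the rest of the family. Fitting only the 6 progenitor arrays ended the calls of these last 2 lists (adjusted p 0.125 and 0.303). Lists that were not called were astroglia (3 of 15 higher, 5 lower; adjusted p 0.582), mesoderm and cardiac (4 of 20 higher, 2 lower; adjusted p 0.394), with Eomes at -0.84 and Actc1 at 1.39, neural crest (4 of 14 higher, 2 lower; adjusted p 0.394), with Snai2 at 0.81, endothelial and blood (1 of 9 higher, 3 lower; adjusted p 0.586), Hox genes (5 of 15 higher, 1 lower; adjusted p 0.0838), with Hoxa2 at 0.80, hypoxia and glycolysis (6 of 23 lower; adjusted p 0.155), and amino acid and ER stress (1 of 24 higher, 7 lower; adjusted p 0.0676). The receptor gene Pdgfra fell by 1.43 (adjusted p 6.42e-10) in the oligodendrocyte list, which was not called (1 of 11 higher, 4 lower; adjusted p 0.584). In all, 1127 genes rose and 1326 fell in -/- progenitors (17.0%), 300 and 309 of them by at least 1.5-fold, and array weights gave 3989 genes in place of 2453. Olig1 had a change of -0.53 (adjusted p 0.0166) that did not pass without +/+ replicate 1 (adjusted p 0.0553), +/+ replicate 2 (0.0627) or -/- replicate 3 (0.0773).

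In neurons the dopaminergic list was higher in -/- cells, the 1 list call of the genotype comparisons that held with an estimated correlation. Of 24 members 13 rose and none fell (16 and 0 adjusted over the list alone), with a median of 0.56 (adjusted p 4.80e-14, adjusted p = 0.00492 with an estimated correlation). Ddc, which makes dopamine and serotonin from their precursors, rose by 1.63 (SE 0.07, adjusted p 1.28e-09), Corin, a floor plate protease, by 1.60 (SE 0.17, adjusted p 8.74e-06), Aldh1a1 by 1.55 (SE 0.12, adjusted p 5.07e-07) and Foxa1 by 1.47 (SE 0.14, adjusted p 4.08e-06). Th, the rate-limiting enzyme of dopamine synthesis, rose by 1.25 (SE 0.17, adjusted p 0.000114) and the dopamine transporter gene Slc6a3 by 0.82 (SE 0.13, adjusted p 0.000351); these 2 members were named after their values were seen. Nr4a2, which specifies these neurons, had a change of 0.55 that did not pass (adjusted p 0.166), as did the vesicular transporter Slc18a2 (0.36, adjusted p 0.105).

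Cell cycle and endoderm genes were lower in -/- neurons and mesenchymal genes higher. Of 31 cell cycle genes 19 fell and none rose (24 and 0 adjusted over the list alone; median -0.30; adjusted p 8.18e-11, adjusted p = 0.236 with an estimated correlation), with the replication genes Cdc6 at -0.58 (SE 0.07, adjusted p 5.23e-05) and Mcm5 at -0.55 and the mitotic kinase Aurkb at -0.48. Of 23 endoderm genes 14 fell and none rose (1 and 14 adjusted over the list alone; median -0.33; adjusted p 4.47e-10, adjusted p = 0.0785 with an estimated correlation). Sox17 fell by 1.26 (SE 0.12, adjusted p 4.84e-06), and the epithelial genes Epcam and Krt18 by 1.10 and 1.05. Of 33 mesenchymal genes 17 rose and 6 fell (20 and 6 adjusted over the list alone; median 0.42; adjusted p 2.15e-07, adjusted p = 0.25 with an estimated correlation), with Tgfbi at 1.20 and the collagen Col6a3 at 1.16 above and the matrix gene Ccn2 at -0.99 below. Of 23 interferon genes 10 fell and none rose (1 and 11 adjusted over the list alone; median -0.27; adjusted p 9.28e-06, adjusted p = 0.130 with an estimated correlation), with Ifit1 at -0.83 (adjusted p 0.00338) and Usp18 at -0.79. Of 14 glutamatergic and GABAergic genes 4 fell (7 adjusted over the list alone), with the interneuron gene Lhx6 at -0.53 (adjusted p 0.00777, adjusted p = 0.100 with an estimated correlation).

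The largest single changes in -/- neurons were again led by Tmem267, which rose by 2.81 (adjusted p 2.52e-09), and Mid1, which fell by 1.99 (SE 0.17, adjusted p 1.11e-06). The potassium channel subunit gene Abcc9 rose by 2.04 (SE 0.12, adjusted p 1.42e-08), Tph2, the neuronal enzyme of serotonin synthesis, by 1.72 (SE 0.12, adjusted p 1.40e-07), the gap junction gene Gjb6 (chromosome 14) by 1.71, the leptin receptor Lepr by 1.58 and the fatty acid receptor Cd36 by 1.57. Ptger3 fell by 1.79 (adjusted p 3.61e-07), Tspan8 by 1.35 and the pluripotency-associated Fbxo15 by 1.27. The linker histone gene H1f2 fell by 0.68 (adjusted p 3.04e-05), though another of its probe sets went the other way. It is 1 of 2 measured linker histones, a list too short for a test; H1f10 had a change of -0.17 (adjusted p 0.300).

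Among the other lists in neurons, the Y-linked genes Uty, Kdm5d and Eif2s3y rose by 0.66, 0.49 and 0.42 (adjusted p 0.00372, adjusted p = 0.0785 with an estimated correlation). Of 32 genes near Hmgn1 on chromosome 16, 7 fell (10 adjusted over the list alone), with the kinase Ripk4 at -0.83 and the reductase Cbr3 at -0.74 (adjusted p 0.019, adjusted p = 0.215 with an estimated correlation). This call ended without +/+ replicate 2 (adjusted p 0.0601). Of 28 chromatin remodeller and histone variant genes 1 rose and 5 fell (1 and 9 adjusted over the list alone; adjusted p 0.0298, adjusted p = 0.249 with an estimated correlation), with the deacetylase Hdac9 at 0.50 and Hmga2 at -0.49. That call ended without +/+ replicate 2 (adjusted p 0.0767), without -/- replicate 2 (0.0788), with only the neuron arrays (0.0658) and with quantile normalization (0.0583). Pan-neuronal genes had 5 of 36 lower, among them the neurofilament genes Nefm and Nefl (both chromosome 14) at -0.74 and -0.58 (adjusted p 0.0609), and DNA methylation and Polycomb genes 6 of 25 lower (adjusted p 0.183). Astroglial genes had 5 of 15 higher and 2 lower (adjusted p 0.135). In all, 858 genes rose and 1049 fell in -/- neurons (13.2%), 236 and 175 of them by at least 1.5-fold.

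**Figure D3:**
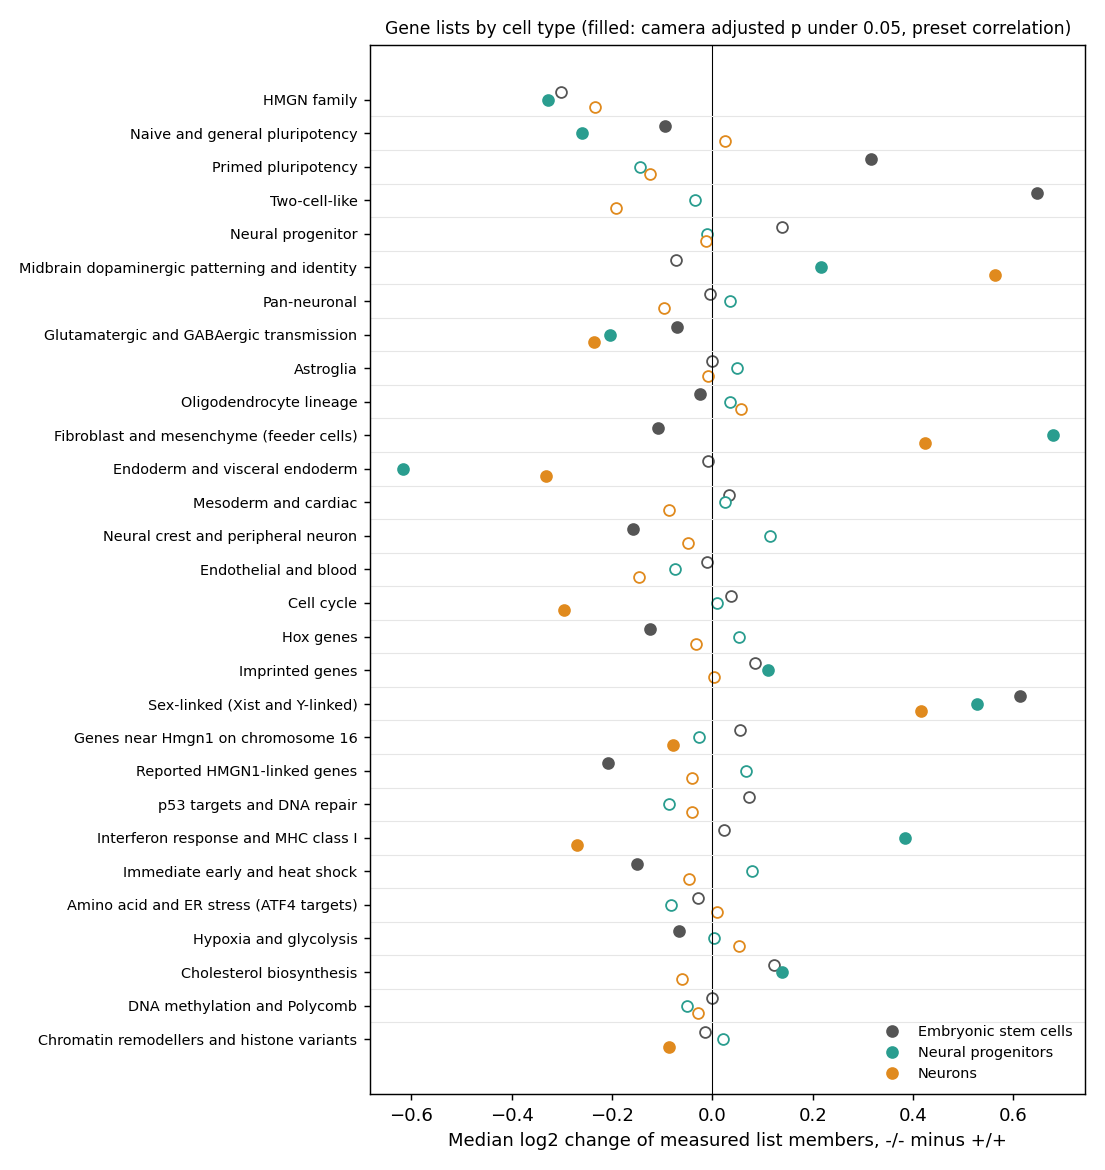
Median log2 change, -/- minus +/+, of the measured members of each tested gene list (vertical axis) in the 3 cell types; filled points passed camera's test at an adjusted p under 0.05 with the preset correlation, open points did not. The dopaminergic list in neurons, at 0.56, is the 1 filled point that also passed with an estimated correlation.

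Whether the genotype effect itself differed between cell types was tested with the interactions. The effect on Olig1 and Olig2 was higher in progenitors than in ES cells by 4.43 (SE 0.20, adjusted p 1.33e-09) and 4.22 (adjusted p 5.19e-11). Since their -/- ES cell means lay under the background bound, these sizes and their rank are uncertain, and with group means under the bound raised to it they were 3.41 for Olig1 and 2.52 for Olig2. Of the 30 largest interactions 25 had a group mean under the bound. Raised to it in the same way, the difference between neurons and ES cells for Tspan8 was -1.44 in place of -2.23. Ntn1 changed by -0.91 in ES cells and by 1.17 in neurons, a difference of 2.08. The intestinal and pancreatic genes Tspan8 and Spink1 changed by 0.89 each in ES cells and by -1.35 and -1.04 in neurons. Between progenitors and neurons the effects on 3 interferon-induced genes turned: Rtp4 changed by 1.71 in progenitors and -0.73 in neurons (difference -2.44), and Usp18 and Ifit1, chosen for this test after their values were seen, had differences of -2.01 (adjusted p 6.87e-06) and -1.78 (adjusted p 0.000169). Ankrd1, a stretch-responsive gene, changed by 1.05 in progenitors and -1.15 in neurons. The effect on Th was higher in neurons than in progenitors by 1.21 (SE 0.24, adjusted p 0.00403). The effect differed for 2358 genes between progenitors and ES cells (824 higher in progenitors, 1534 lower), for 1599 between neurons and progenitors (818 and 781) and for 2260 between neurons and ES cells (679 and 1581). Quantile normalization gave 792 and 1045 for the last (43.1% higher, against 30.04%), and with only the arrays compared there were 1270.

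Progenitors and neurons shared more of the measured genotype effect with each other than with ES cells. Called changes of at least 2-fold numbered 17 in ES cells, 182 in progenitors and 95 in neurons, and ES cell arrays spread more widely. Both can lower a correlation or overlap with ES cells, and how far they did was not tested. Across the 14433 genes, which are not independent replicates, the effect in progenitors correlated with that in neurons at r 0.362 (rho 0.176, jackknife SE 0.0363), the effect in ES cells with that in progenitors at r 0.0459 (rho 0.00821, SE 0.0256) and with that in neurons at r 0.0449 (rho 0.0306, SE 0.0360). Without chromosome 14 these were 0.358, 0.0193 and 0.0258. Both progenitors and neurons had 270 genes higher, where independence gives 67.0 (p 1.39e-99, Fisher exact test), and 329 genes lower, where it gives 96.4 (p 3.10e-101). For ES cells and progenitors 171 genes were lower in both, where independence gives 57.3 (p 1.21e-41), and 181 higher in both, where it gives 119 (p 2.74e-09). Without chromosome 14 these were 54 lower, where it gives 29.9 (p 2.54e-05), and 172 higher, where it gives 111 (p 2.16e-09). In all 3 cell types 40 genes rose and 50 fell, Tmem267 and Mid1 among them, where independence gives 7.06 and 4.17, and 34 of the 50 lie on chromosome 14. A further 88 genes changed in all 3 but not in the same direction, where independence gives 36.9. These expectations for all 3 cell types ignore the overlap between progenitors and neurons given above, so the excesses over them in part restate that overlap. The effect of the genotype was also set against differentiation steps that share no arrays with it. In ES cells it correlated with the change from +/+ progenitors to +/+ neurons at r -0.0782 (rho -0.0992, SE 0.0138; r -0.0463 with quantile normalization and -0.0644 without a filter), in progenitors with the change from +/+ ES cells to +/+ neurons at r 0.108 (rho 0.110, SE 0.0176), and in neurons with the change from +/+ ES cells to +/+ progenitors at r 0.010 (rho 0.0227, SE 0.0361).

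The step from ES cells to neural progenitors in +/+ cells lowered pluripotency genes and raised neural ones. Fabp7, a fatty acid binding protein of radial glia, rose by 9.11 (SE 0.08, adjusted p 8.08e-21), the neural transcription factor Zic1 by 7.56, the endoderm factor Sox17 by 7.27 and the collagen Col3a1 by 6.95. Nanog fell by 6.01 (SE 0.12, adjusted p 1.10e-16), Tdgf1 by 6.49 and Dnmt3l by 5.88. Of 32 naive and general pluripotency genes 31 fell and none rose, with a median of -3.88 (adjusted p 8.50e-15, adjusted p = 0.00428 with an estimated correlation). Of 26 neural progenitor genes 24 rose (adjusted p 2.28e-08, adjusted p = 0.0785 with an estimated correlation), with Cdh2 at 6.09. Other lineages rose too: 32 of 33 mesenchymal genes (adjusted p 1.92e-10, adjusted p = 0.198 with an estimated correlation) and 18 of 23 endoderm genes, with 4 lower (adjusted p 0.00326, adjusted p = 0.272 with an estimated correlation). Of 24 dopaminergic genes 17 rose and 3 fell (adjusted p 0.00847, adjusted p = 0.198 with an estimated correlation), with Shh at 5.02 and Foxa2 at 4.63, and all 17 cholesterol genes rose (adjusted p 3.51e-05, adjusted p = 0.0785 with an estimated correlation). Hmgn3 rose by 2.87. In all 5966 genes rose and 5369 fell.

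The step from progenitors to neurons in +/+ cells was led by genes of mature neural cells. The glial water channel Aqp4 rose by 6.74 (SE 0.09, adjusted p 4.65e-18), Gad1 by 6.55 (SE 0.14, adjusted p 5.78e-16) and the glutamate receptor Grm5 by 6.22. Hmga2, a chromatin protein of early progenitors, fell by 5.0 (SE 0.09, adjusted p 6.15e-17), and the pluripotency genes Pou5f1 and Lin28a by 4.08 and 4.01. Of 36 pan-neuronal genes 34 rose and none fell, with a median of 2.66 (adjusted p 7.08e-15, adjusted p = 0.00492 with an estimated correlation), among them Mapt at 4.72 and Snap25 at 4.40. Of 14 glutamatergic and GABAergic genes 13 rose, with a median of 4.05 (adjusted p 2.91e-07, adjusted p = 0.00877 with an estimated correlation). All 31 cell cycle genes fell, with a median of -2.26 (adjusted p 1.88e-12, adjusted p = 0.198 with an estimated correlation), and of 23 endoderm genes 20 fell and 2 rose (adjusted p 0.000462, adjusted p = 0.214 with an estimated correlation). Corin and the monoamine transporter Slc18a2 rose by 3.37 and 3.17, and Nr4a2 by 1.74. Hmgn1 and Hmgn5 fell by 0.32 and 0.79. In all 4997 genes rose and 6407 fell.

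In -/- cells both steps changed similar numbers of genes. From ES cells to progenitors 5739 rose and 5480 fell, with Fabp7 at 8.92, Nanog at -6.35, Col3a1 at 7.99 and Sox17 at 5.21. Sox17 thus rose less than in +/+ cells, with a difference of -2.05 (SE 0.18, adjusted p 1.10e-06). From progenitors to neurons 5087 rose and 6584 fell, with Gad1 at 7.13, Aqp4 at 6.96, Corin at 4.41 and Pou5f1 at -3.18. The larger rise of Corin in -/- cells, by 1.04, passed the interaction test (adjusted p 0.010).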

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

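The tests of a sequence variant under the Olig probe sets, of chromosome 14 as a whole, of a lower share of neural cells and of a smaller share of endoderm cells were chosen after the results they bear on had been seen, as was the look at oligodendrocyte markers above background alone. The other tests in this part were fixed before the results they measure were seen.

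Olig1 and Olig2, neighbours on chromosome 16, fell in -/- ES cells to values under the background bound. Down to that bound the smaller fall was 2.85, while in -/- progenitors and neurons the largest fall of either was 0.53. A sequence variant under the probe sets would lower the signal wherever the genes are expressed, so the value of 0.53 argues against it. Fewer oligodendrocyte-lineage cells in the cultures would lower the other markers of that lineage, but the 9 others measured had a median change of 0.0024 (quartiles -0.04 and 0.09), and the 6 of them above the background bound in +/+ ES cells had -0.01 (quartiles -0.15 and 0.16, none called), where loss down to the bound would give -1.53. Loss of the surrounding chromosome segment would lower the neighbours, but the 20 nearest tested genes had a median of 0.0615 (quartiles -0.05 and 0.14), with 1 lower and 2 higher, and 19 of them lay above the background bound. A difference in the control of these 2 genes between the ES cell lines, through Hmgn1 or through another difference between the lines, may remain as a hypothesis that these arrays do not test, and a share of oligodendrocyte-lineage cells too small to show against the ES cells' own expression of these markers was not tested.

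In all 3 cell types 40 genes rose and 50 fell in -/- cells, and 88 more changed in all 3 in mixed directions. A segment carried along with the targeted Hmgn1 allele would place such genes near Hmgn1. Of the 66 nearest tested genes 0 changed the same way in all 3, a share of 0% against 0.620% elsewhere (one-sided Fisher exact p 1). Apart from Hmgn1 itself, none of the 40 and 50 genes thus lay there, and a segment there does not account for them. With so low a share elsewhere, 0 of 66 cannot tell whether a segment was carried. Variants under single probe sets would leave other probe sets of the same gene unmoved. Of the genes with another probe set, 44 of 44 had the others on average in the same direction (100%, lower 95% limit 92.0). The test scored only the direction and could not reach genes with no other probe set. On chromosome 14, where most genes lay below 0, a shared direction says little about variants. A lower dosage of the whole of chromosome 14 in the -/- line predicts lower medians along its whole length, and all 30 blocks of its genes over the 3 cell types had medians below 0. The value of 30 is consistent with such a dosage difference, which may be carried by part of the cells and could account for the 34 of the 50 lower genes that lie there, but not for the others.

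Endoderm genes were lower and mesenchymal genes higher in -/- progenitors and neurons. A lower share of neural cells alone would raise the markers of both other types. The higher of the 2 endoderm medians was -0.33, with -0.62 in progenitors and -0.33 in neurons. The mesenchymal medians were 0.68 and 0.42. Lower endoderm genes were part of the pattern itself, so this outcome was fixed in advance. It says only that a lower neural share alone would not give the pattern. A lower neural share beside another change was not tested. A smaller share of endoderm cells predicts most of the list below 0: 73.9% of the members were in progenitors (lower 95% limit 51.6) and 91.3% in neurons (lower limit 72.0), so the prediction was met, though it comes close to restating the pattern. A second test, chosen after that result and the members' values had been seen, asked whether any member rose: Rbp4, a retinol carrier of the visceral endoderm, did by 1.03 in progenitors and Afp by 0.51, but 2 of 23 members are too few to argue against a smaller share of endoderm cells of every kind. A smaller share of endoderm cells and a larger share of mesenchymal cells may remain, as may a change within the cells, and the design cannot separate these.

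The genotype effect differed between progenitors and ES cells for 2358 genes by the interaction test. The differences of the log2 effects, progenitors minus ES cells, were 4.43 for Olig1, 4.22 for Olig2, 2.65 for Prl2a1, 2.59 for Prl7b1, 2.58 for Prl7d1, -2.74 for Ptger3, -2.67 for Car8, -2.23 for Tspan8, -2.20 for Enpep and -2.18 for Hs3st1. Between neurons and progenitors it differed for 1599 genes. These differences, neurons minus progenitors, were 2.20 for Agtr2, 1.68 for Gulo, 1.67 for Gjb6, 1.62 for Car8, 1.61 for Abcc9, -2.51 for Prl7b1, -2.44 for Rtp4, -2.26 for Prl2a1, -2.19 for Ankrd1 and -2.16 for Prl7d1. Between neurons and ES cells it differed for 2260 genes. Here the differences, neurons minus ES cells, were 4.93 for Olig1, 4.58 for Olig2, 2.10 for Abcc9, 2.08 for Ntn1, 1.96 for Corin, -2.23 for Tspan8, -1.92 for Spink1, -1.74 for Uba1y, -1.71 for Hs3st1 and -1.66 for Ptger3. Of these 30 differences 25 had a group mean under the background bound, so their sizes and ranks are uncertain. Both differences of Abcc9 lost their call without the filter on dim probe sets.

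Among 4579 probe sets with no single gene name, which no comparison used, a signal of the genotype also appeared: 210 changed in -/- ES cells (151 higher, 59 lower), 200 in progenitors (85 higher, 115 lower) and 159 in neurons (91 higher, 68 lower).

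Each comparison was also counted over other splits of its arrays. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and in each of the 7 comparisons of groups only the real split, 1 of 10, gave as many genes. The real and the highest other numbers were 2144 and 37 in ES cells, 2453 and 0 in progenitors, 1907 and 2 in neurons, 11335 and 0 for progenitors against ES cells in +/+ cells and 11219 and 0 in -/- cells, and 11404 and 0 for neurons against progenitors in +/+ cells and 11671 and 0 in -/- cells. In these 7 comparisons every other split mixed the groups compared. It thus put their difference into the spread, so low other numbers are in part built in. For the interactions 100 of the 200 splits within both cell types were drawn. Between progenitors and ES cells 2 of these 100 gave as many as the real 2358, the highest other being 2584, between neurons and progenitors 1 (real 1599, highest other 1148), and between neurons and ES cells 1 (real 2260, highest other 2172). The share under 0.05 in each excludes chance only for arrays with no genotype effect at all, and says little about the interaction itself, since a split that mixes the genotypes puts their difference into the spread. The large other numbers came from a structure of the samples: the splits with 2584 and 2172 kept the genotypes apart in both cell types with the labels swapped in 1, the split with 1148 kept them apart in 1 cell type, and splits that kept them apart in neither gave at most 2.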

How the results depend on the processing

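No pseudocount, a pseudocount of 16, the omission of chromosome 14 and that of Olig1 and Olig2 were chosen after the data were seen, and the other alternatives before. Of the numbers of genes under them, 140 stayed within 1.5 times the reported number and 20 did not. With only the arrays compared there were 237 genes in ES cells (153 higher, 84 lower) and 1270 for neurons against ES cells in the interaction. Progenitors and neurons, refitted in the same way, stayed within 1.5 times, so fewer arrays alone do not account for the fall in ES cells. The SD of an array from the mean of its group mates was 0.162 to 0.196 in ES cells. It was 0.111 to 0.127 in progenitors and 0.133 to 0.160 in neurons. Whether this wider spread caused the fall was not tested. Array weights gave 1126 in ES cells and 3989 in progenitors, and the cause was not tested. A fold change of at least 1.5 left 131, 609 and 411 in ES cells, progenitors and neurons, 6590 and 6574 for the 2 steps in +/+ cells, 6646 and 6776 in -/- cells, and 821, 613 and 635 for the interactions of progenitors with ES cells, neurons with progenitors and neurons with ES cells. An adjusted p under 0.01 left 804, 1485 and 973 in the 3 cell types and 1186, 712 and 881 for these interactions. Both are stricter by construction. The effects in ES cells and progenitors correlated at 0.0193 without chromosome 14, and the effect in ES cells with the +/+ step from progenitors to neurons at -0.0644 without a filter and -0.0463 with quantile normalization, against the reported 0.0459 and -0.0782; the cause was not tested. Of 145 list tests 54 were called, and 4 with an estimated correlation: the dopaminergic list in neurons, the naive list from ES cells to progenitors, and the pan-neuronal and transmission lists from progenitors to neurons. An estimated correlation above the preset 0.01 widens a test, and one below it narrows the variance used. The repeat also rested on the 12 residual degrees of freedom in place of a number set by the genes. That weakens small p-values at any correlation, so the lost calls cannot be put down to correlation within the lists alone. Mbd1 in ES cells reversed to -0.0014 with the mean of its probe sets, and Tbx20 in progenitors to -0.0435 without a filter, both near 0. Of the named genes, 7513 values under these alternatives kept their direction and side of the threshold, 190 were no longer past it and 1 newly was. Of the single list tests under the other settings, 806 kept their side, 60 lost the call, most of them with the estimated correlation, and 4 gained it.

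Leaving out 1 array at a time gave 1437 to 2222 genes in ES cells, 1809 to 1892 in progenitors, 1300 to 1607 in neurons, 10857 to 11039 and 10838 to 11137 for the steps in +/+ cells, 10782 to 10918 and 11188 to 11323 in -/- cells, and 1836 to 2498, 1185 to 1516 and 1672 to 2436 for the interactions in the order above. The correlations between genotype effects lay within 0.0341 to 0.0572, 0.0278 to 0.0651 and 0.329 to 0.370, those with differentiation within -0.0817 to -0.0686, 0.0961 to 0.121 and -0.0192 to 0.0279, and the called list tests were 50 to 56. Of the named genes, 3523 values kept their side of the threshold and 269 did not, and of the list tests 849 kept it, 10 lost the call and 11 gained it. Replicate numbers did not pair the arrays (correlations of -0.178 to 0.0713 for the 9 same-number pairs within a cell type, and -0.259 to 0.257 for the 45 over all groups), and a block for them gave 1950 genes in ES cells. Signal near the background limits the dimmer genes, such as the prolactins in +/+ cells.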

Other observations

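The lists of prolactin, serotonergic and placental genes below were made after members of each had been seen to change, so no p-value is given for them. In -/- progenitors all 4 measured prolactin family genes, which placental cells express, rose from near background, with a median of 2.45, and in ES cells and neurons none of the 4 passed. All 4 lie on chromosome 13, as do Ctsj and Tmem267. Of 17 placental trophoblast genes 4 rose and 2 fell in progenitors. Those that rose were the protease gene Ctsj by 2.26, Tpbpa by 1.62, the keratin Krt7 by 0.82 and the X-linked homeobox gene Rhox9 by 0.78. Those that fell were the trophoblast regulator Cdx2 by 0.57 and the X-linked Rhox6 by 0.26. In neurons 1 rose, Ctsj by 0.51, and 3 fell, Krt7 by 0.91, Rhox6 by 0.87 and Rhox9 by 0.49. Both group means of Ctsj in neurons lay under the background bound, so that rise is uncertain.

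Of 13 genes of serotonergic neurons, a list made once Tph2 and Ddc had been seen, 6 rose and none fell in -/- neurons, with a median of 0.44. Tph2 rose by 1.72, the serotonin transporter gene Slc6a4 by 1.49, Ddc by 1.63, the monoamine oxidase Maob by 0.89, the transcription factor Lmx1b by 0.64 and Gch1 (chromosome 14), which makes a cofactor of monoamine synthesis, by 0.59. Ddc, Lmx1b, Gch1, Slc18a2 and Foxa2 also stand in the dopaminergic list. In -/- progenitors 4 of the 13 rose, among them Tph2, whose group means there both lay under the background bound.

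Chromosome 12 was the next after chromosome 14 in the share of genes that fell, with 98 of 515 in progenitors (19%, adjusted p 2.43e-11), 67 in neurons (13%, adjusted p 2.61e-05) and 24 in ES cells (4.66%). The shift was not even along it. In 10 blocks of its genes in order, the progenitor medians were 0.037, -0.014 and 0.016 in blocks 1 to 3. They lay between -0.13 and -0.048 in blocks 4 to 10. On chromosome X, 87 of 479 genes rose in -/- ES cells (18.2%, adjusted p 1.42e-05), as did 4 of 6 on chromosome Y (adjusted p 0.0194). In -/- progenitors more genes rose on chromosome 13 (63 of 531, 11.9%, adjusted p 0.0112) and chromosome 3 (73 of 691, 10.6%, adjusted p 0.0426) than elsewhere. In -/- neurons this held for chromosome 3 (63 of 691, 9.12%, adjusted p 0.0112), chromosome 10 (63 of 707, 8.91%, adjusted p 0.0125) and chromosome Y (3 of 6, adjusted p 0.0384).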
